A study of Homo sapiens with 12 samples.

How the data were processed

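The samples were 12 total RNA preparations from human fibroblasts with control or EWS-targeting shRNA, stimulated 2 days after plating of 100000 cells per well with 2 µg/ml of an agonistic LTBR antibody and lysed at 0, 2 or 6 h, per the labels' protocols. Each sample has a deposited file of raw nCounter counts for 269 probes: 255 genes, 8 negative and 6 positive controls. The 255 gene counts are unnormalized, per the file headers and their differing totals. The authors' table of the whole series holds log2 values. DESeq2 is named in the submitters' processing notes, with its version and function not given in the sources used here. Compared with these values, a regularized log transform computed here with the groups known differed by at most 0.0893 (median 0.00348) over the 269 probes, and one blind to the groups by up to 0.79 (median 0.0442). This comparison fits the table to a computed transform and does not establish the authors' step. The table's column medians lay between 5.9 and 6.03. It was used only as an alternative. Gene totals ran from 406495 to 710449 counts per library, and the control probes held 10.9% to 13.9% of all counts.

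Groups were taken from the sample titles. The main test used R 4.3.3 with edgeR 4.0.16. Genes with at least 20 counts in at least 2 libraries were kept (178 of 255), library totals over these genes were scaled by TMM, and 6 group means were fitted to all 12 libraries by the robust quasi-likelihood method, leaving 6 residual degrees of freedom. Contrasts of these means gave 10 comparisons: the 2 h and 6 h response with each shRNA, the shRNAs at each of 3 times and averaged, and the difference of the responses at 2 h and 6 h. P-values were two-sided and adjusted by Benjamini-Hochberg over the 178 genes of a comparison, with a threshold of 0.05. The common biological coefficient of variation was 3.64%. Intervals and errors cover only the spread between these libraries. A gene was called at background in a group when its counts lay at or below the mean plus 2 SD of the negative controls. A fold against such a group is given as a lower bound.

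Genes were named by a rule fixed before the data were examined. It took up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold and, between 2 groups, without overlap of their libraries. It added up to 4 members of each list with the smallest p, or 2 where none had passed, and RELA, RELB, NFKB1 and the reference genes. Named outside it, after their values were seen, were CXCL6 at 2 h with control shRNA and FOS and DDIT3 at 2 h with EWS shRNA. The same holds for IL8 at 0 h between shRNAs, IL8, CXCL2, OXER1 and FXYD2 in the 2 h difference, and MX1 in the EWS shRNA 6 h libraries. All genes called in the 2-group comparisons had no overlap between libraries, except at 6 h between shRNAs, where 58 of 60 had none. Chance gives 33.3% of unselected genes. The calls came from these same libraries, so the lack of overlap is no separate support for them. Of the symbols, 253 are current in the RefSeq table of GRCh38.p14 and 2 matched through synonyms. No genome build is given in the sources used here, so no coordinates are given.

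The 20 gene lists were also fixed before the data were examined, and 19 are reported: ELR+ CXC chemokines, CC chemokines, interferon response, NF-kB subunits and regulators, canonical NF-kB inducible and noncanonical NF-kB associated genes, interleukins and colony-stimulating factors, complement, prostaglandin and leukotriene genes, AP-1, MYC and stress transcription factors, Toll-like receptors and innate sensors, the MAP kinase cascade, TGF-beta and growth factor genes, cytokine receptors, MEF2 and chromatin genes, macrophage, T cell and granulocyte markers, and panel reference genes. The 17 with at least 3 tested members were tested on edgeR's log2 CPM (prior count 2) with limma 3.58.1: camera with a preset correlation of 0.01, adjusted over 170 tests that include the list not reported, again with an estimated correlation, and fry. The size of the response was compared by fry on the difference of responses, with each gene weighted by the sign of its mean response over both shRNAs, among genes past the threshold for that mean. Its p was adjusted over the 2 times, a step added after the data were examined. Some lists share members, so list results are not independent of each other. The canonical NF-kB inducible list shares CXCL1 and CXCL3 with the ELR+ CXC chemokines and CCL2 with the CC chemokines. It also shares TNFAIP3 with the NF-kB regulators, and IL6 and CSF2 with the interleukins.

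The tests were checked on simulated data. Counts for the 178 genes were drawn 20 times with 40 genes changed. For the 2 h response with control shRNA, 53% of 1.25-fold, 76.5% of 1.5-fold, 94.5% of 2-fold and 100% of 4-fold changes were recovered. For the difference of the 2 h responses these shares were 41%, 67%, 76.5% and 94%. Between shRNAs at 0 h they were 51%, 78%, 92.5% and 100%, and for the average over the times 73%, 93%, 99.5% and 100%. Between 1.05% and 1.23% of unchanged genes were called. A shifted list was found by camera in 100% of draws, and 4.41% of unshifted lists had p under 0.05. Genes were drawn independently of each other, so these shares do not check the list test where genes vary together.

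Alternatives were RLE size factors, total counts, the geometric mean of the 6 reference genes or of the positive controls as the scale, no filter, a filter of 50 counts or of the negative controls, no robust fit, limma-voom, DESeq2 1.42.0, limma on the deposited log2 values, the replicate number as a block, and each library left out in turn. A lone library of a group was then assumed to vary like the other groups. Added after seeing the data were the average without the 6 h libraries, the interferon list without the EWS shRNA 6 h libraries, and the size of the response with positive control scaling. The design has no unstimulated libraries at 2 and 6 h and a single shRNA against EWS as labelled, so time in culture and off-target effects were not separated.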

Results

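Transcript levels of 255 genes were measured in human fibroblasts that expressed a control short hairpin RNA (shRNA) or an shRNA against EWS, an RNA-binding protein encoded by EWSR1. The cells were taken before stimulation (0 h) and 2 h and 6 h after an agonistic antibody to LTBR, the lymphotoxin beta receptor, which signals through canonical and noncanonical NF-kB. Total RNA was read on an nCounter inflammation panel, in which barcoded probes are counted directly after hybridization, without amplification. The 6 combinations of shRNA and time had 2 libraries each, 12 in all. The question, from the series' title and design, is how EWS knockdown changes the genes that LTBR activates.

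Gene counts per library ran from 406495 to 515152 with control shRNA and from 449635 to 710449 with EWS shRNA. The mean total with EWS shRNA over that with control shRNA was thus 0.978 at 0 h, 1.27 at 2 h and 1.44 at 6 h. Background, the mean plus 2 SD of the 8 negative control probes, lay between 15.6 and 31.7 counts, and between 147 and 169 genes exceeded it in a library. Replicates correlated across genes with r from 0.995 to 0.998 on the log2 scale, where genes are not independent replicates. Each pair differed by more than sampling noise, most at 6 h, where the chi-square per degree of freedom was 7.8 with control and 4.18 with EWS shRNA. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples. EWSR1, LTBR and NFKB2 were not analysed here, so neither the depth of the knockdown nor the level of the receptor was checked. Values are normalized counts as mean ± SD with n = 2, log2 fold changes with their standard error, and adjusted p-values from edgeR over 178 genes. That error is approximate, back-calculated as the absolute log2 fold change over the square root of the quasi-likelihood F statistic.

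After 2 h of the antibody with control shRNA, several chemokine and cytokine transcripts, among them IL8, IL6 and IL11, were higher than at 0 h. IL8 (now named CXCL8), a neutrophil chemokine, went from 222 ± 24.4 to 2511 ± 337 normalized counts, an 11.2-fold rise (log2 3.49 ± 0.18, adjusted p = 4.2e-07). IL6, an acute-phase cytokine, rose 5.62-fold from 336 ± 12.8 to 1886 ± 66.5 (log2 2.49 ± 0.07, adjusted p = 1.4e-19). TNFAIP3, which encodes the NF-kB inhibitor A20, rose 4.34-fold from 287 ± 5.41 to 1249 ± 18.7 (log2 2.12 ± 0.07, adjusted p = 1.4e-17). IL11, a cytokine of the IL-6 family, rose by a log2 of 2.00 ± 0.08 and PTGS2, the inducible cyclooxygenase, by 1.12 ± 0.06. In all, 45 of 178 genes passed the threshold, 29 higher and 16 lower.

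Of 13 tested genes on the list of canonical NF-kB inducible genes, 11 rose and 0 fell at 2 h with control shRNA (11 adjusted over the list alone; camera adjusted p = 1.4e-09, but 0.155 with an estimated correlation). Besides those above, CCL2, a monocyte chemokine, rose by 0.81 ± 0.05 on the log2 scale and the NF-kB subunit genes RELB and NFKB1 by 0.80 ± 0.09 and 0.35 ± 0.07. Of 6 neutrophil-attracting ELR+ CXC chemokines, 4 rose (4 adjusted over the list alone; camera adjusted p = 0.000494, 0.155 with an estimated correlation), with log2 changes of 2.10 ± 0.10 for CXCL1, 2.04 ± 0.18 for CXCL3 and 1.72 ± 0.17 for CXCL2. Transcripts of CXCL1, CXCL2 and CXCL3 are similar in sequence, so the split of counts between them is uncertain. Of 9 NF-kB subunits and regulators 5 rose (5 adjusted over the list alone; camera adjusted p = 0.0191, 0.30 with an estimated correlation). CC chemokines, with 1 of 3 higher (1 adjusted over the list alone; 0.32), and interleukins and colony-stimulating factors, with 3 of 10 higher (3 adjusted over the list alone; 0.0715), did not pass as lists. Outside these lists, SMAD7, an inhibitor of TGF-beta signalling, rose by 0.93 ± 0.06, the chemokine receptor gene CXCR4 by 1.08 ± 0.19, and the AP-1 and MAF family genes JUN and MAFF by 0.77 ± 0.07 and 0.78 ± 0.12. Among the genes that fell, the log2 change was -0.67 ± 0.09 for the interferon-induced gene IFIT2 and -0.57 ± 0.07 for DDIT3, a transcription factor of the stress response. FOS, the immediate-early AP-1 subunit, changed by -0.54 ± 0.11 (adjusted p = 0.000583), a call that ended when libraries were scaled by the spiked positive controls (adjusted p = 0.0755).

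**Figure D1:**
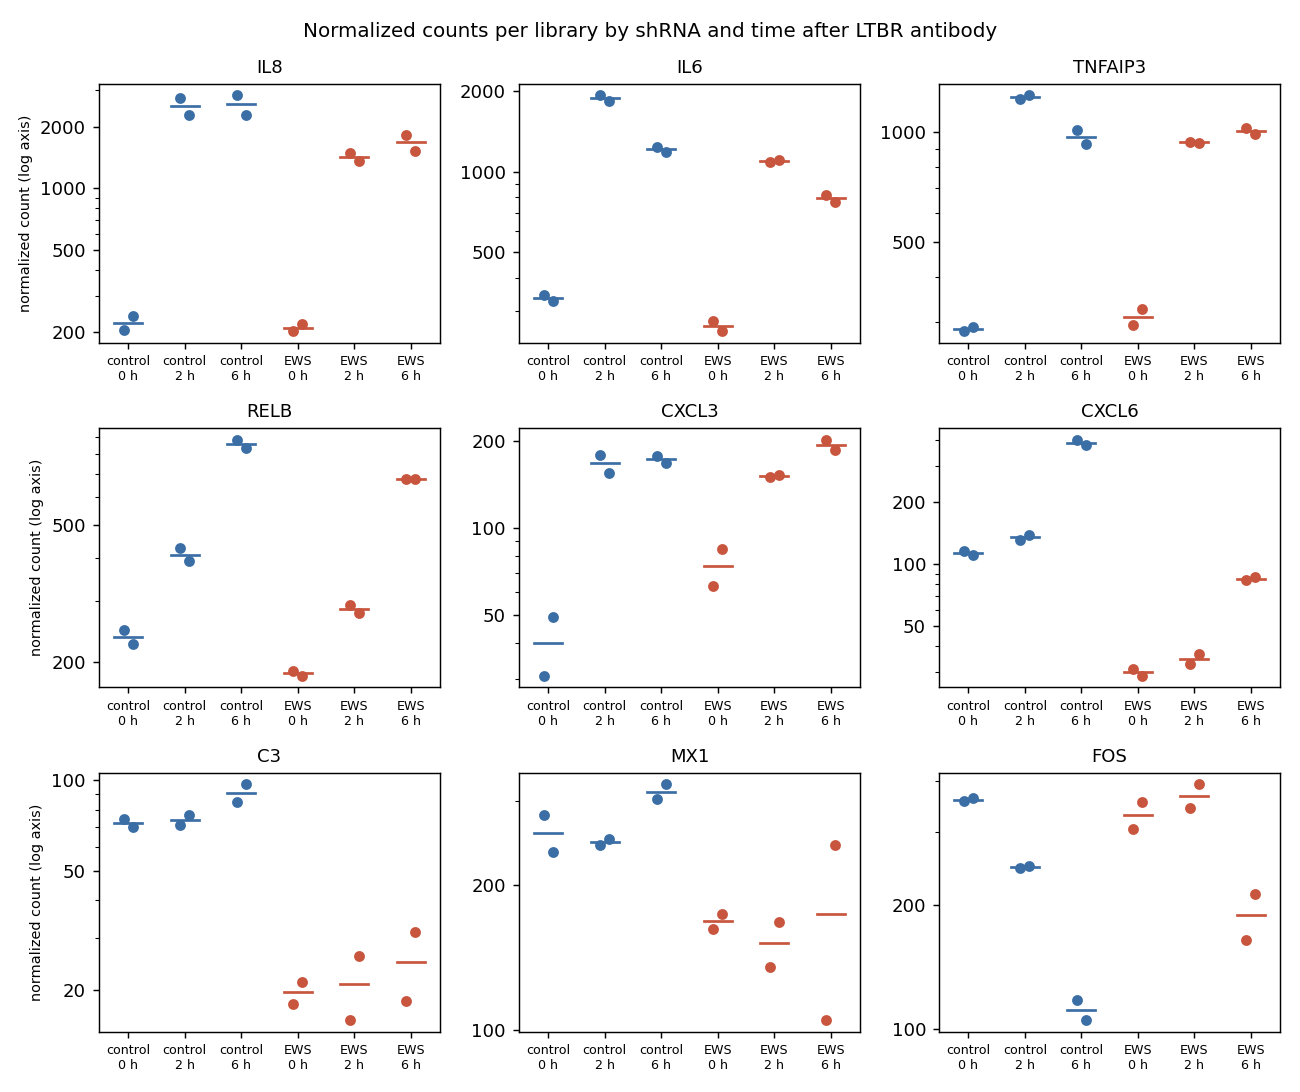
Normalized counts (vertical log axis) of 9 genes in the 12 libraries by shRNA and time after the LTBR antibody; points are libraries and lines the means of 2. IL8 reached 2511 at 2 h with control and 1420 with EWS shRNA, and CXCL6 and C3 were lower with EWS shRNA at 0, 2 and 6 h.

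By 6 h with control shRNA, 74 genes passed the threshold, 37 higher and 37 lower. IL8 stood at 2561 ± 387 normalized counts, 11.5-fold above 0 h (log2 3.52 ± 0.17, adjusted p = 2.0e-07). RELB, the partner of the noncanonical NF-kB subunit, rose 3.65-fold from 236 ± 14.8 to 859 ± 30.8 (log2 1.87 ± 0.08, adjusted p = 9.5e-16). The chemokine CXCL6 rose 3.43-fold from 114 ± 3.58 to 391 ± 16.8 (log2 1.78 ± 0.11, adjusted p = 8.9e-13), while at 2 h its log2 change of 0.25 ± 0.13 had not passed (adjusted p = 0.167). CSF2, which encodes GM-CSF, was at background at 0 h and at least 1.46-fold higher at 6 h (adjusted p = 1.0e-05). FOS dropped from 360 ± 4.48 to 111 ± 8.69 counts (log2 -1.69 ± 0.13, adjusted p = 4.2e-11).

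At 6 h with control shRNA, 12 of 13 canonical NF-kB inducible genes rose (12 adjusted over the list alone; camera adjusted p = 7.9e-08, 0.203 with an estimated correlation), as did all 6 tested ELR+ CXC chemokines (6 adjusted over the list alone; 0.000229, 0.155 with an estimated correlation), among them CXCL5 with 1.94 ± 0.24. NF-kB subunits and regulators rose in 7 of 9 (7 adjusted over the list alone; 0.000457, 0.203 with an estimated correlation), with 0.96 ± 0.07 for NFKB1 and 0.69 ± 0.06 for BIRC2. The 3 tested CC chemokines rose (3 adjusted over the list alone; 0.0237, 0.274 with an estimated correlation), led by CCL7 with 1.96 ± 0.17 and CCL2 with 1.20 ± 0.05. CCL20 was lowest, near background, and its call ended with limma-voom (adjusted p = 0.072), without the robust fit (0.0501) and without control shRNA 0 h replicate 1 (0.0817) or 2 (0.185), EWS shRNA 2 h replicate 1 (0.0504) or 2 (0.0523), or 6 h replicate 1 (0.0579). Interleukins and colony-stimulating factors rose in 5 of 10 (5 adjusted over the list alone; 0.0191, 0.216 with an estimated correlation). The calls of these last 2 lists ended with scaling by the panel's reference genes (0.0515 each), and that of the interleukins also without control shRNA 0 h replicate 1 (0.0504). Interferon response genes were lower in 6 of 12, with -0.90 ± 0.09 for IFIT1 and -0.60 ± 0.09 for IFIT2, but as a list they did not pass (camera adjusted p = 0.0684). Other genes that fell were MAP2K6, a p38 kinase activator (-1.12 ± 0.22), TLR3, a sensor of double-stranded RNA (-0.83 ± 0.19), the prostaglandin receptor gene PTGFR (-0.77 ± 0.08) and IL1R1, the interleukin-1 receptor (-0.65 ± 0.06).

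With EWS shRNA, 28 genes passed at 2 h, 24 higher and 4 lower, and 59 at 6 h, 37 higher and 22 lower. IL8 went from 210 ± 11 to 1420 ± 88.2 normalized counts at 2 h (6.76-fold, log2 2.76 ± 0.18, adjusted p = 4.9e-06) and 1676 ± 214 at 6 h. IL6 rose 4.16-fold from 264 ± 15.9 to 1097 ± 11.9 at 2 h (log2 2.06 ± 0.07, adjusted p = 5.0e-17). RELB rose from 186 ± 4.05 to 285 ± 11.6 at 2 h and 678 ± 1.2 at 6 h, where its log2 change was 1.87 ± 0.08. CSF2 was at background at 0 h and reached 47.6 ± 12.9 at 2 h and 111 ± 20.2 at 6 h, at least 1.9-fold and 4.43-fold higher. Canonical NF-kB inducible genes rose in 11 of 13 at both times (11 at 2 h and 13 at 6 h adjusted over the list alone; camera adjusted p = 6.3e-12 at 2 h and 1.4e-09 at 6 h, 0.155 at each with an estimated correlation). ELR+ CXC chemokines rose in 4 of 6 at 2 h and 6 of 6 at 6 h (4 and 6 adjusted over the list alone; 0.00157 and 0.000256, 0.155 at each with an estimated correlation). MAP2K6 (-1.23 ± 0.19), IFIT1 (-0.93 ± 0.08), FOS (-0.79 ± 0.11) and PTGFR (-0.59 ± 0.08) fell at 6 h. The count at 2 h was 48 with a filter of 50 counts in place of 20.

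The smaller lists behaved as follows with EWS shRNA. NF-kB subunits and regulators rose in 3 of 9 at 2 h and 6 of 9 at 6 h (3 and 6 adjusted over the list alone; camera adjusted p = 0.0226 and 0.000533, 0.302 and 0.203 with an estimated correlation). The 2 h call ended without EWS shRNA 0 h replicate 2 (adjusted p = 0.0532) or 2 h replicate 1 (0.0542). At 6 h, CC chemokines rose in 2 of 3 (3 adjusted over the list alone; 0.0226, 0.274 with an estimated correlation), and the list fell under 3 tested members without control shRNA 6 h replicate 1 or EWS shRNA 6 h replicate 2. Interleukins and colony-stimulating factors rose in 4 of 10 at 6 h (5 adjusted over the list alone; 0.0478, 0.274 with an estimated correlation). That call ended with reference gene scaling (0.0772), with the replicate block (0.0563) and without control shRNA 2 h replicate 1 (0.0503), 6 h replicate 1 (0.0596) or 6 h replicate 2 (0.0581). Interferon response genes were lower in 5 of 12 and higher in 1 at 6 h (6 and 1 adjusted over the list alone; 0.0335, 0.493 with an estimated correlation), with -0.76 ± 0.09 for IFIT2 and -0.40 ± 0.06 for STAT2. Their call ended without control shRNA 6 h replicate 1 (0.0539) or 2 (0.0561) or EWS shRNA 6 h replicate 1 (0.11). The EWS shRNA 6 h libraries stood apart in this list: normalized counts of MX1, an interferon-induced antiviral gene, were 105 and 243.

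Responses under the shRNAs shared most genes. At 2 h, 23 genes rose under both, of 29 with control and 24 with EWS shRNA, where independent lists would share 3.91, and 3 fell under both, of 16 and 4 (0.36). At 6 h, 30 rose under both, of 37 each (7.69), and 22 fell under both, of 37 and 22 (4.57). No library is shared between these comparisons. Across all 178 genes, which are not independent replicates, log2 changes correlated with r = 0.845 at 2 h and 0.917 at 6 h.

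**Figure D2:**
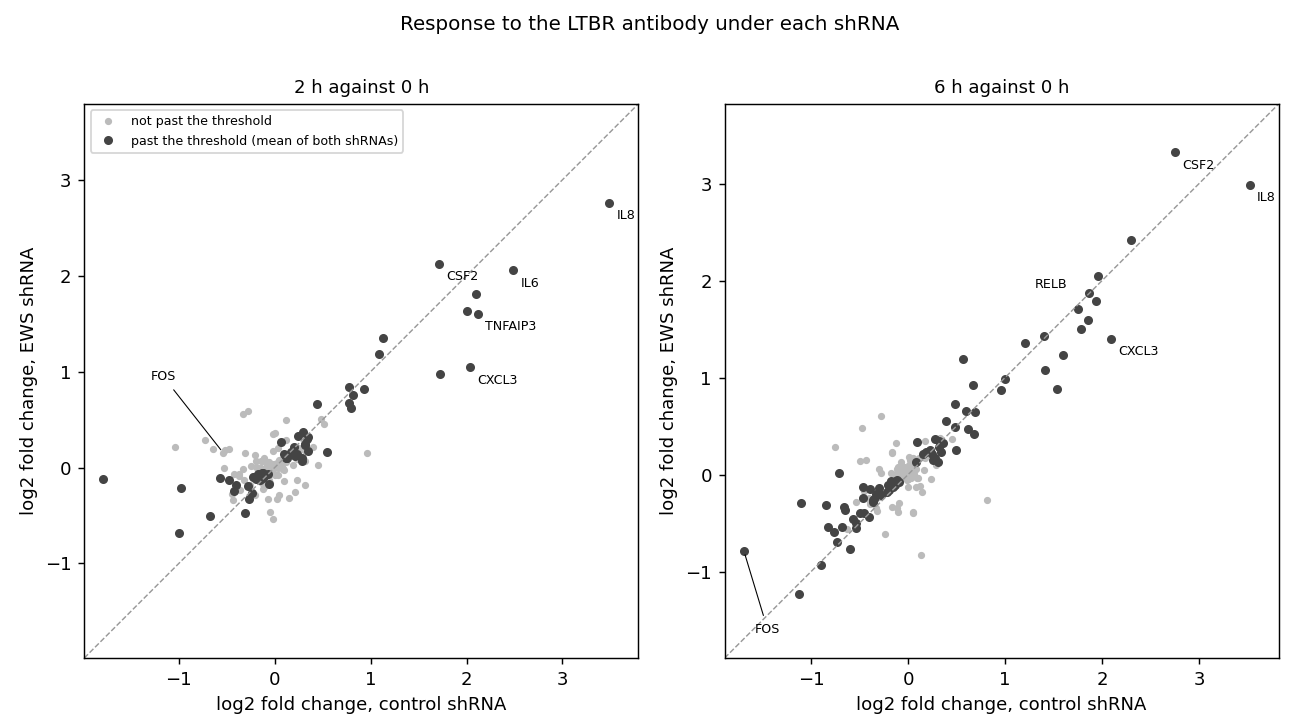
Log2 fold change of each gene after the LTBR antibody with control shRNA (horizontal) and EWS shRNA (vertical), at 2 h (left) and 6 h (right); dark points passed the threshold on the mean of both responses and the dashed line marks equal change. At 2 h, IL8, IL6, TNFAIP3 and CXCL3 lie below the line, and FOS lies above it at both times.

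The change of response with EWS shRNA was tested directly, as the difference between the EWS and the control response. At 2 h, 5 genes passed. TNFAIP3 rose 3.03-fold with EWS shRNA, from 309 ± 22 to 937 ± 4.54, against 4.34-fold with control (log2 difference -0.52 ± 0.11, adjusted p = 0.007). IL6 had a difference of -0.43 ± 0.11 (adjusted p = 0.0201) and CXCL3 of -0.99 ± 0.25 (0.023). CXCL3 started higher with EWS shRNA, at 73.8 ± 15 against 40 ± 12.9 counts, and reached 152 ± 1.6 against 168 ± 16.9. FOS changed by 0.16 ± 0.10 with EWS and by -0.54 ± 0.11 with control shRNA (difference 0.69 ± 0.15, adjusted p = 0.007), and DDIT3 by -0.11 ± 0.07 and -0.57 ± 0.07 (difference 0.46 ± 0.10, adjusted p = 0.007). Differences for IL8 and CXCL2 were -0.73 ± 0.28 and -0.74 ± 0.23 and did not pass. The TNFAIP3 call held in all 24 alternatives, with adjusted p up to 0.0406.

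For the other 4 genes, 1 library or tool ended the call. The CXCL3 call ended with DESeq2 (adjusted p = 0.074), limma-voom (0.057) and without control shRNA 0 h replicate 1 (0.15) or 2 h replicate 1 (0.14), or EWS shRNA 0 h replicate 2 (0.15) or 2 h replicate 2 (0.053). That of IL6 ended without control shRNA 0 h replicate 2 (0.22) or 2 h replicate 1 (0.12), or EWS shRNA 0 h replicate 1 (0.18) or 2 h replicate 2 (0.053). FOS at 2 h did not pass with positive control scaling (0.28), DESeq2 (0.074) and without control shRNA 2 h replicate 1 (0.051), EWS shRNA 0 h replicate 1 (0.051) or 2 h replicate 2 (0.053). DDIT3 did not pass with positive control scaling (0.59), DESeq2 (0.078) and without control shRNA 0 h replicate 1 (0.07), EWS shRNA 0 h replicate 1 (0.057) or 2 h replicate 1 (0.053). The count of 5 became 3 without control shRNA 0 h replicate 1 or EWS shRNA 0 h replicate 1, and 2 without control shRNA 2 h replicate 1 or EWS shRNA 2 h replicate 2. With DESeq2 it was 3, with the stricter filter 9 and on the deposited log2 values 8.

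At 6 h only FOS passed the test of the difference, among 178 genes in edgeR. Its log2 change was -1.69 ± 0.13 with control and -0.79 ± 0.11 with EWS shRNA (difference 0.90 ± 0.17, adjusted p = 0.00416), and the 0 h libraries are the same as in its 2 h difference. The call ended with positive control scaling (adjusted p = 0.11), where 1 other gene passed, with DESeq2 (0.081, 0 genes) and without control shRNA 6 h replicate 2 (0.18, 0 genes). Without control shRNA 6 h replicate 1, 12 genes passed, and without EWS shRNA 6 h replicate 2, 2. The stricter filter gave 2 and the deposited log2 values 6. At an unadjusted p under 0.05 there were 18 genes at 2 h and 16 at 6 h. IL8 (-0.53 ± 0.27), IL6 (-0.26 ± 0.11) and RELB (0.00 ± 0.11) did not pass at 6 h.

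As lists, ELR+ CXC chemokines responded less at 2 h with EWS shRNA, with a median log2 difference of -0.51 and 1 of 6 members past the threshold (2 adjusted over the list alone, camera adjusted p = 0.00301, 0.17 with an estimated correlation). Of its members, CXCL2 (0.56 ± 0.19, edgeR adjusted p = 0.0289) and CXCL3 (0.85 ± 0.21, 0.00388) were already higher with EWS shRNA at 0 h, calls lost in 4 and 2 of 24 alternatives. Neither was called lower at 2 h, and CXCL5 and CXCL6 did not pass as responding at 2 h on the mean of both shRNAs. Canonical NF-kB inducible genes had a median of -0.056 and 3 of 13 members smaller (4 smaller and 1 larger adjusted over the list alone; 0.0437, 0.499 with an estimated correlation). That last call ended with reference gene scaling (0.0629), with fry (0.158) and without control shRNA 0 h replicate 1 (0.0677) or 2 (0.0534), 2 h replicate 1 (0.073) or 2 (0.0604) or 6 h replicate 2 (0.057), or EWS shRNA 0 h replicate 1 (0.0512) or 2 (0.0948), 2 h replicate 2 (0.18) or 6 h replicate 1 (0.0505). Over the 58 genes that responded at 2 h on the mean of both shRNAs, 35 up and 23 down, the response was smaller with EWS shRNA in 44 (median log2 difference -0.077, limma's fry, adjusted p = 0.0172 over the 2 times). Over 82 such genes at 6 h it was smaller in 58 (median -0.058, adjusted p = 0.0172), with medians of -0.099 for the 41 falling and -0.031 for the 41 rising genes, whose median rise was 0.61 with control and 0.66 with EWS shRNA. With positive control scaling the medians were -0.255 at 2 h and -0.196 at 6 h. The 2 h result no longer passed without control shRNA 0 h replicate 2 (adjusted p = 0.0563) or 2 h replicate 2 (0.0552), or EWS shRNA 0 h replicate 1 (0.0911), 0 h replicate 2 (0.0738) or 2 h replicate 1 (0.0591). That at 6 h no longer passed with reference gene scaling (0.0681) and without control shRNA 0 h replicate 2 (0.0563), EWS shRNA 0 h replicate 1 (0.202) or 2 (0.0738), 2 h replicate 1 (0.0631) or 6 h replicate 2 (0.253).

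Levels also differed between EWS and control shRNA at each time point, including before stimulation. At 0 h the chemokine gene CXCL6 was 3.79-fold lower with EWS shRNA, at 30 ± 1.57 against 114 ± 3.58 normalized counts (log2 -1.92 ± 0.17, adjusted p = 3.9e-09). CCL2 was 2.07-fold lower, at 1211 ± 22.6 against 2507 ± 56.4 (log2 -1.05 ± 0.06, adjusted p = 4.0e-13). The complement genes C1R and C1S were lower by log2 -0.91 ± 0.05 and -0.69 ± 0.05, and C3, the central complement component, was at background with EWS shRNA and at least 2.88-fold lower (adjusted p = 5.4e-06). HMGB2, a chromatin protein gene, was higher by 0.54 ± 0.07, as were the matrix metalloproteinase gene MMP3 (0.53 ± 0.06), the cyclooxygenase gene PTGS1 (0.51 ± 0.08), MEF2D (0.44 ± 0.06) and JUN (0.40 ± 0.07). The largest called rise at 0 h was that of MAP3K9, of the MAP kinase cascade list (edgeR, adjusted p = 0.000114). This gene was dim, at 37.9 ± 6.84 normalized counts with EWS shRNA. CXCL3 was higher by 0.85 ± 0.21 (adjusted p = 0.00388), a call that ended without control shRNA 0 h replicate 1 (0.081) or EWS shRNA 0 h replicate 2 (0.067). In all, 49 genes differed at 0 h (21 higher, 28 lower), 57 at 2 h (27 higher, 30 lower) and 60 at 6 h (31 higher, 29 lower).

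The lower genes were largely shared between the times, which have no library in common. At all 3 times, 19 genes were lower, where independent lists would share 0.769, and 13 higher (0.555). Of the 19, CXCL6, CCL2, C1R, C1S and C3 kept their call at each time in all 24 alternatives, as did HMGB2, MMP3, PTGS1, JUN and MEF2D of the 13. The 19 also hold CCL7, MASP1, OAS2, IL6, RELB and NFKB1, whose 0 h calls ended with positive control scaling (adjusted p from 0.125 for CCL7 to 0.938 for NFKB1). With that scaling 7 of the 19 stayed lower at 0 h, namely C1R, C1S, C3, CCL2, CXCL6, IL1R1 and MX2. The 0 h calls of all the others ended. Gene totals over the positive controls were 232 and 228 in the control 0 h libraries and 274 in each EWS shRNA 0 h library. Positive control scaling carries this gap into the 0 h folds. Without control shRNA 0 h replicate 1 the 0 h calls of CCL7 (0.0843), OAS2 (0.116), IL6 (0.0803), RELB (0.143) and NFKB1 (0.131) ended, and without replicate 2 that of OAS2 (0.0939). Without EWS shRNA 0 h replicate 1 those of CCL7 (0.0504), OAS2 (0.229), RELB (0.0504) and PTGER3, one of the 13 (0.0516), ended, and without replicate 2 those of CCL7 (0.0915), IL6 (0.0915), RELB (0.0915) and NFKB1 (0.0516). With DESeq2 CCL7 (0.0869), OAS2 (0.177), RELB (0.119) and NFKB1 (0.0584) did not pass at 0 h. OAS2 failed in 10 and RELB in 7 of the 24 at 0 h, and OAS2 also at 2 h without EWS shRNA replicate 1 (0.0613) and at 6 h without control shRNA replicate 2 (0.0686). IL8 did not pass at 0 h (-0.09 ± 0.24) but was lower at 2 h (-0.82 ± 0.14) and 6 h (-0.62 ± 0.13). IL6 was lower by -0.78 ± 0.06 at 2 h, CXCL6 by -2.19 ± 0.11 at 6 h. CSF2 was higher at 6 h by 1.49 ± 0.22 and at 2 h by at least 1.85-fold, a 2 h call lost without EWS shRNA 2 h replicate 1 (adjusted p = 0.067). The 0 h count fell to 28 or 31 without control shRNA replicate 1 or 2 and to 26 or 31 without EWS shRNA replicate 1 or 2, and the 2 h count to 36 without EWS shRNA 2 h replicate 1. Scaling by positive controls gave 37 genes at 2 h and 33 at 6 h.

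Among the lists, interferon response genes were lower with EWS shRNA in 7 of 12 at 0 h, 4 at 2 h and 5 at 6 h (8, 4 and 5 adjusted over the list alone), with MX2 at log2 -0.92, -0.95 and -0.98. Camera gave adjusted p = 0.0193, 0.0496 and 0.012 (0.44, 0.51 and 0.409 with an estimated correlation). With positive control scaling, 7 of all tested genes were lower at 0 h, and MX2 was the only member of this list among them. The 2 h call ended with reference gene scaling (0.0705), with the replicate block (0.0549) and on leaving out any of 10 libraries (0.0512 to 0.0861). The 6 h call and the MX2 call at 6 h ended without control shRNA 6 h replicate 2 (0.0561 for the list). Complement genes were lower in 5 of 11 at 0 h and 6 of 11 at 6 h (5 and 6 adjusted over the list alone, with 1 higher at 6 h; 0.0329 and 0.00988, 0.316 and 0.274 with an estimated correlation). Their 0 h call ended with reference gene scaling (0.0629) and without control shRNA 0 h replicate 2 (0.0816), 6 h replicate 1 (0.0529) or 6 h replicate 2 (0.0559), or EWS shRNA 0 h replicate 2 (0.0662). At 2 h 5 were lower and the list did not pass (0.0511). With positive control scaling C1R, C1S and C3 stayed lower at 0 h, while the 0 h calls of MASP1 and CFD ended.

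MEF2 and chromatin genes were higher with EWS shRNA in 5 of 12 at 0 h and in 5, with 1 lower, at 6 h (the same counts adjusted over the list alone; camera adjusted p = 0.0084 and 0.0293, 0.203 and 0.274 with an estimated correlation). Their 6 h call ended with reference gene scaling (0.0515). At 2 h 4 were higher and 1 lower (4 and 1 adjusted over the list alone), and the list did not pass (0.0878). ELR+ CXC chemokines were lower in 3 of 6 at 2 h (3 adjusted over the list alone; 0.0405, 0.274 with an estimated correlation), with CXCL1 at -0.61, and did not pass at 0 h (0.834) or 6 h (0.32). That call ended with reference gene scaling (0.069) and without control shRNA 2 h replicate 1 (0.0588), 6 h replicate 1 (0.0539) or 6 h replicate 2 (0.0561), or EWS shRNA 2 h replicate 2 (0.0581). CC chemokines were lower in 2 of 3 at 6 h (2 adjusted over the list alone; 0.0405, 0.292 with an estimated correlation), with CCL2 at -0.89 and CCL7 at -0.78, and did not pass at 0 h (0.0511) or 2 h (0.116). This call ended with reference gene scaling (0.0705) and without control shRNA 0 h replicate 1 (0.0516), EWS shRNA 0 h replicate 2 (0.0532) or 2 h replicate 1 (0.0537), and could not be tested without control shRNA 6 h replicate 1 or EWS shRNA 6 h replicate 2, which left under 3 members.

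Averaged over the 3 times, with 6 libraries against 6, 93 genes differed, 44 higher and 49 lower with EWS shRNA. CXCL6 was 4.08-fold lower (log2 -2.03 ± 0.09, adjusted p = 5.5e-16), CCL2 2.02-fold (-1.02 ± 0.03, 2.1e-18) and CCL7 1.98-fold (-0.98 ± 0.12, 3.1e-07). Of 11 complement genes 7 were lower (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0293, 0.314 with an estimated correlation), with -0.85 ± 0.03 for C1R, -0.64 ± 0.03 for C1S and -0.43 ± 0.04 for the lectin pathway protease gene MASP1. The complement call ended with reference gene scaling (0.0705) and without control shRNA 0 h replicate 2 (0.0534) or EWS shRNA 0 h replicate 2 (0.0532). Interferon response genes were lower in 11 of 12 (11 adjusted over the list alone; 0.00734, 0.373 with an estimated correlation), among them MX2 (-0.95 ± 0.13), OAS2 (-0.73 ± 0.12) and IFI44 (-0.45 ± 0.07). This count was 4 with positive control scaling and 7 without control shRNA 2 h replicate 2. The EWS shRNA 6 h libraries differed in these genes, with MX2 at 26.3 and 55.1 normalized counts and OAS2 at 49.1 and 81. Averaged over 0 and 2 h alone, 9 members were lower with both EWS shRNA 6 h libraries left out of the fit. With all 6 h libraries left out, 11 were lower in that same average. Both counts compare the same libraries, so their gap does not measure the EWS shRNA 6 h libraries. Of 12 MEF2 and chromatin genes 7 were higher and 1 lower (8 and 1 adjusted over the list alone; 0.0229, 0.274 with an estimated correlation), led by HMGB2 (0.63 ± 0.04) and MEF2D (0.38 ± 0.04).

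NF-kB genes went both ways in the average. RELB was lower by -0.40 ± 0.05, NFKB1 by -0.34 ± 0.04, IL6 by -0.58 ± 0.04 and IL11 by -0.39 ± 0.05, while CSF2 and CXCL2 were higher, CXCL2 by 0.40 ± 0.09, and RELA had 0.05 ± 0.06 (adjusted p = 0.473). Of 13 canonical NF-kB inducible genes 6 were lower and 4 higher (6 and 4 adjusted over the list alone; camera adjusted p = 0.32). PTGER3, a prostaglandin E2 receptor gene, was higher by 0.71 ± 0.08 and PTGS1 by 0.66 ± 0.05. Of 6 reference genes 3 were higher (3 adjusted over the list alone; camera adjusted p = 0.396), with 0.13 ± 0.02 for TUBB and 0.15 ± 0.03 for CLTC, and GAPDH had -0.018 ± 0.021 (adjusted p = 0.473). Their median turned negative with reference gene scaling, which sets their mean to 0.

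**Figure D3:**
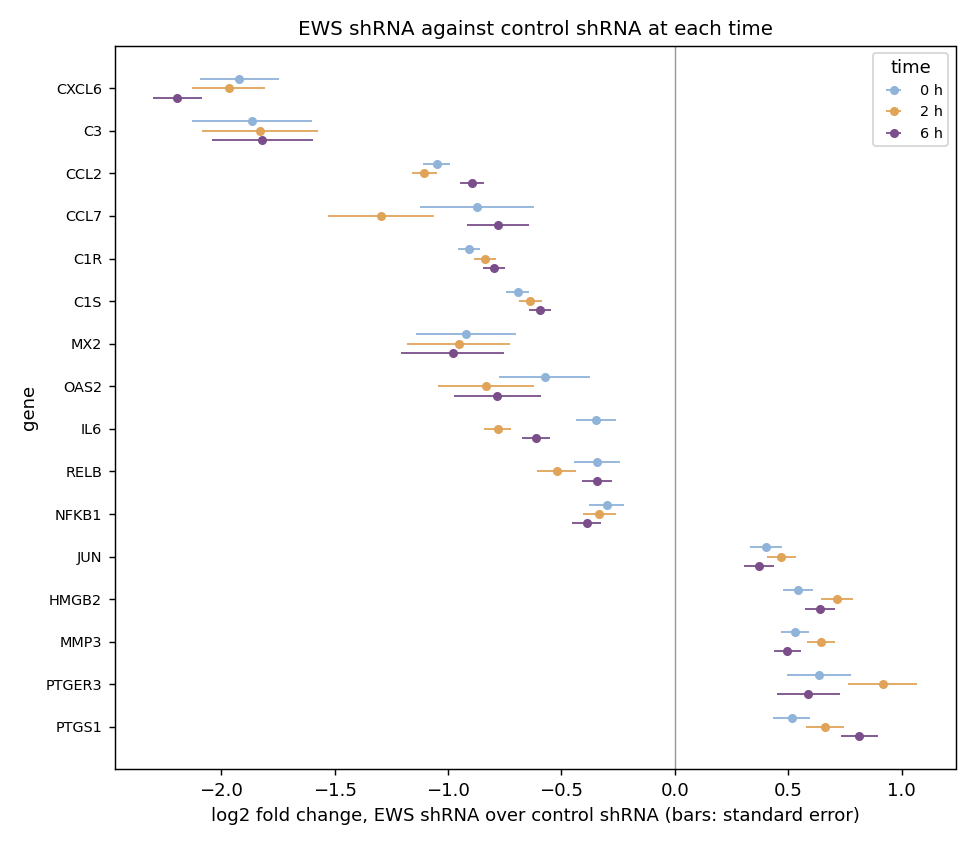
Log2 fold change of 16 genes with EWS shRNA over control shRNA (horizontal axis) at 0, 2 and 6 h; points are edgeR estimates from 2 libraries per group and bars their standard errors. CXCL6 and C3 lie furthest to the left at each time, with CXCL6 at -1.92, -1.97 and -2.19.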

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

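The tests of technical explanations in this part, except the counts of other splits of the libraries, were chosen only after the result was seen.

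The responses to the LTBR antibody differed between the shRNAs by a direct test of the difference. At 2 h this was so for TNFAIP3 (log2 -0.52), DDIT3 (0.46), FOS (0.69), IL6 (-0.43) and CXCL3 (-0.99), and at 6 h for FOS (0.90). The ELR+ CXC chemokines (median -0.51) and the canonical NF-kB inducible genes (median -0.056) differed as lists at 2 h, with the preset correlation alone. Both lists hold CXCL1 and CXCL3, so they are not separate evidence. The size of the response over all responding genes differed at 2 h (median -0.077) and at 6 h (median -0.058). At 6 h the median log2 difference over all tested genes was 0.0528 with TMM and -0.0242 with RLE factors. The weighing of scaling below covers 2 h alone. Of the 18 ways to split the libraries, the real one gave 58 responding genes at 2 h, where the highest other gave 5, and 82 at 6 h, where the highest other gave 1; 1 split each reached the real count. These splits are too few for a share under 0.05.

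The smaller 2 h response with EWS shRNA was weighed against scaling, a higher starting level and a weaker stimulus. For CXCL3 a higher level before stimulation may account for it, with 0.85 at 0 h and -0.145 at 2 h between shRNAs, while for IL6 and TNFAIP3 the tables argue against this, since both were lower with EWS shRNA at 2 h, with log2 -0.41 for TNFAIP3 and -0.78 for IL6. A common scale factor cancels in the mean difference of the rising minus that of the falling genes. This was -0.321 (limma's fry, adjusted p = 0.0331), in the last of 3 tests of scaling tried, and argues only weakly against scaling as the whole cause. The mean of the falling genes leans on the dim genes IL2 (1.67), OXER1 (0.76) and FXYD2 (0.32), and the score was not computed without them. It was negative without each of the 12 libraries (-0.417 to -0.233), but whether it passed depended on single libraries. For rising genes (median -0.069, fry adjusted p = 0.0757) and falling genes (-0.079, fry adjusted p = 0.00224) taken alone, scaling cannot be told apart, as falling genes had 0.114 with positive controls. The scales based on gene counts gave falling genes medians from -0.079 to -0.0419. Relative differences over 14 induced genes were unequal, with 11 smaller and 3 larger (chi-square test of heterogeneity with 13 degrees of freedom, p = 6.56e-05). This test treats genes as independent and the control response as free of error. It leans on PTGS2, larger with EWS shRNA by 0.22 ± 0.09 but not past the threshold itself (edgeR, adjusted p = 0.317). It thus cannot decide on an equal proportional weakening of the stimulus, which stays open. A weaker stimulus with gene-specific dose dependence, a lower receptor level and an effect of EWS itself also stay open and untested.

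The 93 genes that differed between the shRNAs on average were weighed against chance and depth. Of 100 splits drawn from 108, 1, the real one, gave as many genes, and the highest other gave 35. The other splits put libraries of both shRNAs into one group, which widens the spread within groups and lowers their counts. They therefore do not exclude chance differences between the cultures of the 2 shRNAs. Deeper EWS shRNA libraries, 1.27 times at 2 h and 1.44 times at 6 h, are argued against: the genes called at 6 h were already apart in the same direction at 0 h, where the ratio was 0.978 (median 0.223, 55 of 60 genes). An effect of EWS loss, off-target effects of the shRNA and an effect of the shRNAs themselves on interferon signalling stay open and were not tested.

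Interferon response genes differed between the EWS shRNA libraries at 6 h, with MX1 at 105 and 243 normalized counts. Control cells or RNA mixed into replicate 2 are argued against: over 16 other genes the median share moved toward the control level was -0.0155 (upper bound 0.118), where MX2 and OAS2, the 2 interferon genes tested, had 0.493. Replicate 1 was the lower library, with MX2 at 26.3 against 55.1 counts in replicate 2. That it alone makes the lower interferon genes is argued against by the 0 h libraries. There 7 members were lower with TMM (limma's fry for the list, adjusted p = 0.00581), but with positive control scaling MX2 alone kept its 0 h call. Why the libraries differ stays open, and no biological explanation was tested.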

How the results depend on the processing

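The settings with 0 and 2 h alone, without the EWS shRNA 6 h libraries, and positive control scaling of the response size were chosen only after the result was seen. With 2 libraries per group, and a lone library assumed to vary like the other groups, counts near the threshold depend on single libraries. Replicate numbers were not taken to pair the libraries in the main fit. The difference between replicates correlated across genes in 15 pairs of groups with r from -0.0018 to 0.35 (median 0.1), over 0.1 in 7. These values lean positive, with 0.295 for the 0 h groups and 0.265, 0.271 and 0.354 among control 6 h, EWS 2 h and EWS 6 h. A shared effect of the replicate number thus stays open. Probes near background limit folds for dim genes, and 77 of 255 genes were not tested. Named genes kept their call in 355 of 362 cases with limma-voom, 362 of 362 with the replicate block, 303 of 355 with DESeq2, 322 of 362 with reference gene scaling, 252 of 362 with positive control scaling, 330 of 352 with the stricter filter, 344 of 362 on the deposited values and 3970 of 4342 on leaving out a library.

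The stricter filter, which tests fewer genes, gave 48 genes for EWS shRNA at 2 h, 9 for the 2 h difference and 2 for the 6 h difference. Fewer tests alone cannot give the 48, as 39 genes had an unadjusted p under 0.05 in the main edgeR test. The deposited values gave 8 and 6 for the differences and DESeq2 3 and 0. For the 6 h difference 16 genes had an unadjusted p under 0.05 in edgeR. Positive control scaling gave 37 genes between shRNAs at 2 h and 33 at 6 h, and 1 for the 6 h difference, not FOS. It shifted the median of all genes by 0.187 and 0.274 in the control responses, 0.285 between shRNAs at 0 h, -0.192 and -0.23 in the differences and 0.144 in the average, where it gave 70 higher and 22 lower genes against 44 and 49. Reference gene scaling gave 30 higher and 68 lower there. At 0 h between shRNAs these were 63 and 7 with positive controls and 18 and 41 with reference genes, against 21 and 28; RLE factors gave 27 and 21 and total counts 29 and 25. For control shRNA at 2 h positive controls gave 38 higher and 3 lower and reference genes 38 and 8, against 29 and 16, and at 6 h 68 and 8 and 46 and 24, against 37 and 37. For EWS shRNA RLE factors gave 23 and 10 at 2 h, against 24 and 4, and positive controls 30 and 11 at 6 h, against 37 and 22. Between shRNAs reference genes gave 17 and 32 at 2 h, against 27 and 30, and 17 and 45 at 6 h, where RLE factors gave 20 and 31, against 31 and 29. The 2 h difference had 0 higher and 5 lower genes with positive controls, against 2 and 3. Gene totals over the geometric mean of the positive controls were lowest in the control shRNA 0 h libraries, at 232 and 228, against 245 to 304 in the others. Positive control scaling carries this gap into each contrast with those libraries. The average over 0 and 2 h alone gave 89. Of 170 list tests 31 passed, 0 with an estimated correlation and 81 with fry. The response size at 6 h was -0.0457 with reference gene scaling (adjusted p = 0.0681; 0.000329 to 0.253 over its alternatives). Except where an alternative's construction shows it, the cause was not tested.

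Signs turned with positive control scaling for STAT2 (0.032), MKNK1 (0.00998) and GAPDH (0.065) at 2 h and LY96 (0.10), HMGB1 (0.12), HMGN1 (0.13), PGK1 (0.13) and GAPDH (0.18) at 6 h with control shRNA. They also turned for MAX (0.12), LY96 (0.0071), MKNK1 (0.064), MAPK3 (0.099) and IL10RB (0.087) between shRNAs at 0 h, and with reference gene scaling for GAPDH (0.0024) at 6 h with control shRNA.

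On leaving out a library, counts ran from 26 to 57 between shRNAs at 0 h and from 36 to 58 at 2 h, 2 to 6 for the 2 h difference, 0 to 12 for the 6 h difference and 7 to 11 for the interferon members. The response size ran from -0.128 to -0.0669 at 2 h and from -0.0935 to -0.0359 at 6 h, and was -0.255 and -0.196 with positive control scaling. Adjusted p over the alternatives ran from 0.00105 to 0.0406 for TNFAIP3, 0.00184 to 0.275 for FOS, 0.00326 to 0.586 for DDIT3, 0.00105 to 0.218 for IL6 and 0.005 to 0.153 for CXCL3 at 2 h, and from 9.24e-05 to 0.176 for FOS at 6 h.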

Other observations

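The list medians and counts with RLE factors, total counts and positive control scaling were chosen only after the result was seen. Lists that did not pass as a whole still held single genes that differed with EWS shRNA. Averaged over the times, 10 of 19 MAP kinase cascade genes were higher and 4 lower (10 and 4 adjusted over the list alone, camera adjusted p = 0.14). Prostaglandin and leukotriene genes were higher in 4 of 15 and lower in 1 (4 and 1 adjusted over the list alone, 0.204), with LTB4R2, a leukotriene B4 receptor, at 0.51 ± 0.14. Among 16 AP-1, MYC and stress transcription factors 4 were higher, with 0.41 ± 0.07 for FOS, and 4 lower, with -0.30 ± 0.03 for HIF1A, the hypoxia factor, and -0.28 ± 0.03 for CEBPB. Adjusted over the list alone these were 5 and 6, the list did not pass (0.935), and its median turned sign with positive control scaling. Interleukins and colony-stimulating factors were higher in 2 and lower in 4 of 10 (2 and 4 adjusted over the list alone, 0.627), with CSF1, the macrophage growth factor, at -0.37 ± 0.04.

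Of 14 Toll-like receptors and innate sensors 4 were lower (4 adjusted over the list alone, camera adjusted p = 0.406), but with positive control scaling 3 were higher and 0 lower. IL1R1 was lower by -0.42 ± 0.04, among 2 of 7 cytokine receptors (2 adjusted over the list alone, 0.777), a list whose median turned sign with RLE factors, total counts and positive control scaling. TGF-beta and growth factor genes had 1 higher and 1 lower of 9 (1 and 1 adjusted over the list alone, camera 0.878), and their median turned sign with positive control scaling. NF-kB subunits and regulators had 2 higher and 2 lower of 9 (2 and 2 adjusted over the list alone, camera 0.703), and their median turned likewise. ELR+ CXC chemokines had 2 higher and 3 lower of 6 (2 and 4 adjusted over the list alone, camera 0.367), and CC chemokines 2 lower of 3 (2 adjusted over the list alone, camera 0.0924). T cell markers, with 4 tested, did not pass as a list (0.969). Markers of macrophages, T cells and granulocytes reached at most 28, 37 and 29 raw counts in a library, near background. The macrophage and granulocyte lists, with 1 tested member each, and the noncanonical NF-kB list, with 2 of 5, were too small to test.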
